A study of Homo sapiens with 12 samples.

How the data were processed

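Gene expression was measured in HepaRG cells, an established human hepatic cell line that can be brought to a hepatocyte-like state in culture, on 12 Affymetrix whole-transcript arrays of the human genome, 1 array per sample. Per the labels' protocols, cells were differentiated with 1.5% DMSO, kept without DMSO for 24 h, and treated for 30 h with vehicle (0.15% DMSO), 25 nM TCDD, 10 µM alpha-endosulfan, or both pollutants together. The doses within the mixture are not stated separately in the labels. RNA was taken from a single well per sample, per the labels' protocols, and a DNase step was part of the extraction. Each group held 3 samples that the titles call biological replicates. Whether these came from separate differentiations is not given in the sources used here, so p-values measure the spread between these samples.

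The authors deposited a table of 33296 probe sets as intensity values on a linear scale, with 20 to 27 exact zeros per array. The program that summarized and normalized the probes is not given in the sources used here. Array medians ran from 88.2 to 100.9, and upper quartiles from 280.9 on TCDD array 2 to 372 on endosulfan array 3. After the log2 step below, medians over genes ran from 7.217 to 7.547 on the same 2 arrays. Quantile normalization had been planned for values not normalized between arrays. The deposited values were taken as already normalized and their scaling was kept, although array scale still differed. Several counts and splits below changed when quantile normalization was run as an alternative. For arrays, no read depth exists, and the number of arrays limits the precision.

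The design was written for log2 values. Since the table was linear, log2(intensity + 16) was taken, with the offset of 16 chosen after the unit was known. Fold changes are on that scale, which understates changes of dim genes. Between 14.9% and 17.2% of the probe sets of an array lay under the offset. Probe sets were named from the platform's annotation: 19459 had a single gene symbol, 1754 had several and 12083 were not listed there and stay unnamed. Of the single-symbol probe sets, 19428 matched an entry of RefSeq's human gene table (assembly GRCh38.p14) by Entrez identifier, and no symbol changed. The build behind the array design is not given in the sources used here, so no coordinates are printed. For the 769 genes with several probe sets, the probe set with the highest mean over the 12 arrays was used, which left 18416 genes. Members of families with near-identical sequences, such as CYP2B6 and its pseudogene CYP2B7P, ADH1A to ADH1C, the UGT2B enzymes and the metallothioneins, can share hybridization signal.

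A model with a mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom), and 6 comparisons were taken from it: each treatment against vehicle, the mixture against each single compound, and the departure from additivity, which is the mixture minus TCDD minus endosulfan plus vehicle on the log2 scale. P-values are 2-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons, the threshold, 37 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. The preset correlation assumes nearly independent genes. Adjusted p-values for lists cover the 37 lists of a comparison.

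Named genes followed that rule. Against vehicle, these were the 10 largest increases and 10 largest decreases among genes past the threshold whose 3 treated arrays all lay on one side of the 3 vehicle arrays. In the other comparisons they were the 5 largest each way, or the 5 smallest p-values each way where none passed. A preset group of 21 genes, of which 16 were measured by a single-symbol probe set, and up to 4 members of each list with the smallest p-values were added. Probe sets with no symbol or several were not named.

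The scripts were tested on simulated arrays with 200 genes changed among the 18416, the noise of each gene drawn independently. For TCDD against vehicle, 43.3% of genes changed by 0.5 on the log2 scale, 94% of those changed by 1 and 100% of those changed by 2 were recovered, and 7.1% of all calls were false. For the departure from additivity, the recovered shares were 7.5%, 71.6% and 100%. For comparisons sharing the vehicle arrays, 100 sets of unchanged groups were simulated, and another 100, added after the data were seen, for the mixture against the sum of the single changes.

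Other settings chosen in advance were quantile normalization, subtraction of array medians, removal of the dimmest 33.3% of genes, all probe sets, the mean of a gene's probe sets, a trended and robust variance prior, a fit of only the groups compared, the replicate number as a block, a 1.5-fold minimum, array weights, and leaving out each of the 12 arrays. Offsets of 4 and 64, array weights estimated gene by gene, and removal of the 3 arrays with extreme upper quartiles (TCDD 2, endosulfan 3 and mixture 2) were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.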

Results

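Expression was measured on 12 arrays of differentiated HepaRG cells, in 4 groups of 3: vehicle, TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a dioxin that binds the aryl hydrocarbon receptor, AhR), the organochlorine insecticide alpha-endosulfan, and both compounds together. The series addresses what combined persistent organic pollutants do to gene expression in these cells. Within a group, arrays correlated at 0.9822 to 0.9942 across probe sets, and between groups at 0.9687 to 0.9942. No pair of arrays held identical values. Values below are group means of the deposited intensity ± SD (n = 3) or log2 fold changes ± SE from limma, with adjusted p-values over 18416 genes.

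TCDD raised most of the measured AhR targets, and its 3 largest increases were among them. CYP1B1 (probe set 8051583), a cytochrome P450 of the CYP1 family, went from 151 ± 8.19 with vehicle to 7475 ± 374 with TCDD, a 44.7-fold increase (log2 5.48 ± 0.12, adjusted p = 1.47e-16). CYP1A2 (probe set 7984862) rose 42.4-fold, from 80 ± 13.5 to 4031 ± 125, and CYP1A1 (probe set 7990391) rose 33.5-fold, from 148 ± 27.8 to 5435 ± 313 (adjusted p = 2.17e-15 and 1.36e-15). ALDH3A1, an aldehyde dehydrogenase, rose 6.36-fold, and TIPARP, a mono-ADP-ribosyltransferase, rose 3.78-fold. NQO1, which is also on the list of NRF2 targets, had a small change (99.1 ± 20.7 to 124 ± 18.9), and AHRR was not measured by a single-symbol probe set. Of the 9 measured AhR targets, 7 rose and 2 did not pass, with a median log2 change of 1.92 (camera adjusted p = 1.07e-39, and 0.000758 with an estimated correlation; 7 also passed when adjusted over the list alone). Other large increases were seen for STC2 (stanniocalcin 2), whose vehicle intensity of 5.81 lay below the offset so that its 8.47-fold change is understated, and for TMEM156, MB21D2, SLC37A2, MBL2 (a mannose-binding lectin of the complement system) and IGFBP1, with log2 changes from 1.95 to 2.82.

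The genes lowered by TCDD included members of several lists of hepatic metabolism. DKK1, a Wnt antagonist, fell 5.2-fold (log2 -2.38 ± 0.14, adjusted p = 2.25e-09), and G6PC1, the catalytic subunit of glucose-6-phosphatase (probe set 8007429), fell from 1475 ± 117 to 338 ± 30.9 (log2 -2.08 ± 0.13, adjusted p = 9.89e-09). CYP4B1, MFSD2A, RDH16 (a retinol dehydrogenase), PFKFB1, HAO2, GNMT (glycine N-methyltransferase), CCN2 and CXCL13 followed, with log2 changes between -1.78 and -1.49. In the list of gluconeogenesis and glycogen genes, 6 of 14 fell and none rose (10 fell when adjusted over the list alone), among them SLC2A2 (the glucose transporter GLUT2, log2 -1.40), GYS2 (liver glycogen synthase, -0.97) and PCK2 (-0.96). PCK1 fell by 0.56 on the log2 scale, and FBP1 had a value of 0.12 that did not pass (adjusted p = 0.784). Among 17 alcohol and aldehyde dehydrogenases, 6 fell and 1 rose (10 and 2 when adjusted over the list alone), with ADH4 at -1.40, ADH6 at -0.84, ADH1C at -0.83 and ALDH8A1 at -0.82. ADH1A (-0.72) and ADH1B (-0.63) also fell. The ADH1A call was lost under 9 alternative settings, among them subtraction of array medians, the PCK1 call under 5 and the ADH1B call under 1, without vehicle replicate 2. For these lists and the 3 that follow, the camera calls rest on the preset correlation. With an estimated correlation the adjusted p was 0.307 for each of the gluconeogenesis, dehydrogenase, coagulation, bile acid and CAR/PXR lists. By fry, which asks another question than camera, their adjusted p ran from 0.00287 to 0.0158.

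Coagulation factors fell in 6 of 21 cases (10 fell and 1 rose when adjusted over the list alone), led by HRG (-0.65) and plasminogen, PLG (-0.70). In the bile acid list, 5 of 16 fell and 1 rose (8 and 1 over the list alone). The sodium-bile acid cotransporter SLC10A1 had a log2 change of -1.35 and AKR1D1, a steroid 5-beta-reductase, rose by 1.25. Targets of the xenobiotic receptors CAR and PXR went both ways, with 7 of 14 lower and 1 higher over all genes and over the list alone. THRSP had a log2 change of -1.36, CYP2C8 of -0.95, CYP3A43 of -0.83 and CYP3A5 of -0.60. CYP3A4 was lower by a smaller amount (9409 ± 664 against 7072 ± 434, log2 -0.41 ± 0.10, adjusted p = 0.0414), a call lost under 15 alternative settings, among them subtraction of array medians, and CYP2B6 was higher (log2 0.53 ± 0.12, adjusted p = 0.0187), a call lost under 6. Albumin did not pass (log2 -0.10 ± 0.11, adjusted p = 0.76). CYP3A4 and albumin, at 9409 and 11627 with vehicle, were among the brightest genes, and array maxima ran from 14727 to 16805. Whether signal is compressed at such intensities was not tested, so larger decreases of both are not excluded. Markers of other cell types gave single calls: KRT19 (biliary) had a log2 change of -0.75 that was lost under 8 settings, quantile normalization among them, POSTN and LUM (mesenchymal) of -0.76 and 0.78, and KDR (endothelial) of -1.13.

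Lists passing upward with TCDD included the NRF2 targets, the antioxidant response genes, of which SLC7A11 (1.16), SRXN1 (0.62) and GCLM (0.56) rose among 17 (4 over the list alone; camera adjusted p = 3.57e-07, and 0.307 with an estimated correlation). The GCLM call was lost under 2 settings. In the cell cycle list no member passed over all genes and 2 over the list alone, with 23 of 25 values above 0 and a median of 0.16 (camera adjusted p = 9.92e-08, and 0.307 with an estimated correlation).

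Across all genes, TCDD changed 452, with 112 higher and 340 lower (24.8% higher). With quantile normalization the split was 240 higher and 435 lower (35.6% higher). The count was 261 without vehicle replicate 1, 235 without vehicle replicate 2 and 273 without TCDD replicate 2, and 272 of the 452 genes changed at least 1.5-fold. By camera 23 of the 37 lists passed, 6 upward and 17 downward, while with an estimated correlation only the AhR targets did. When the same 6 arrays were divided otherwise into 3 and 3, up to 12 lists passed, though such divisions keep part of the treatment difference.

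**Figure D1:**
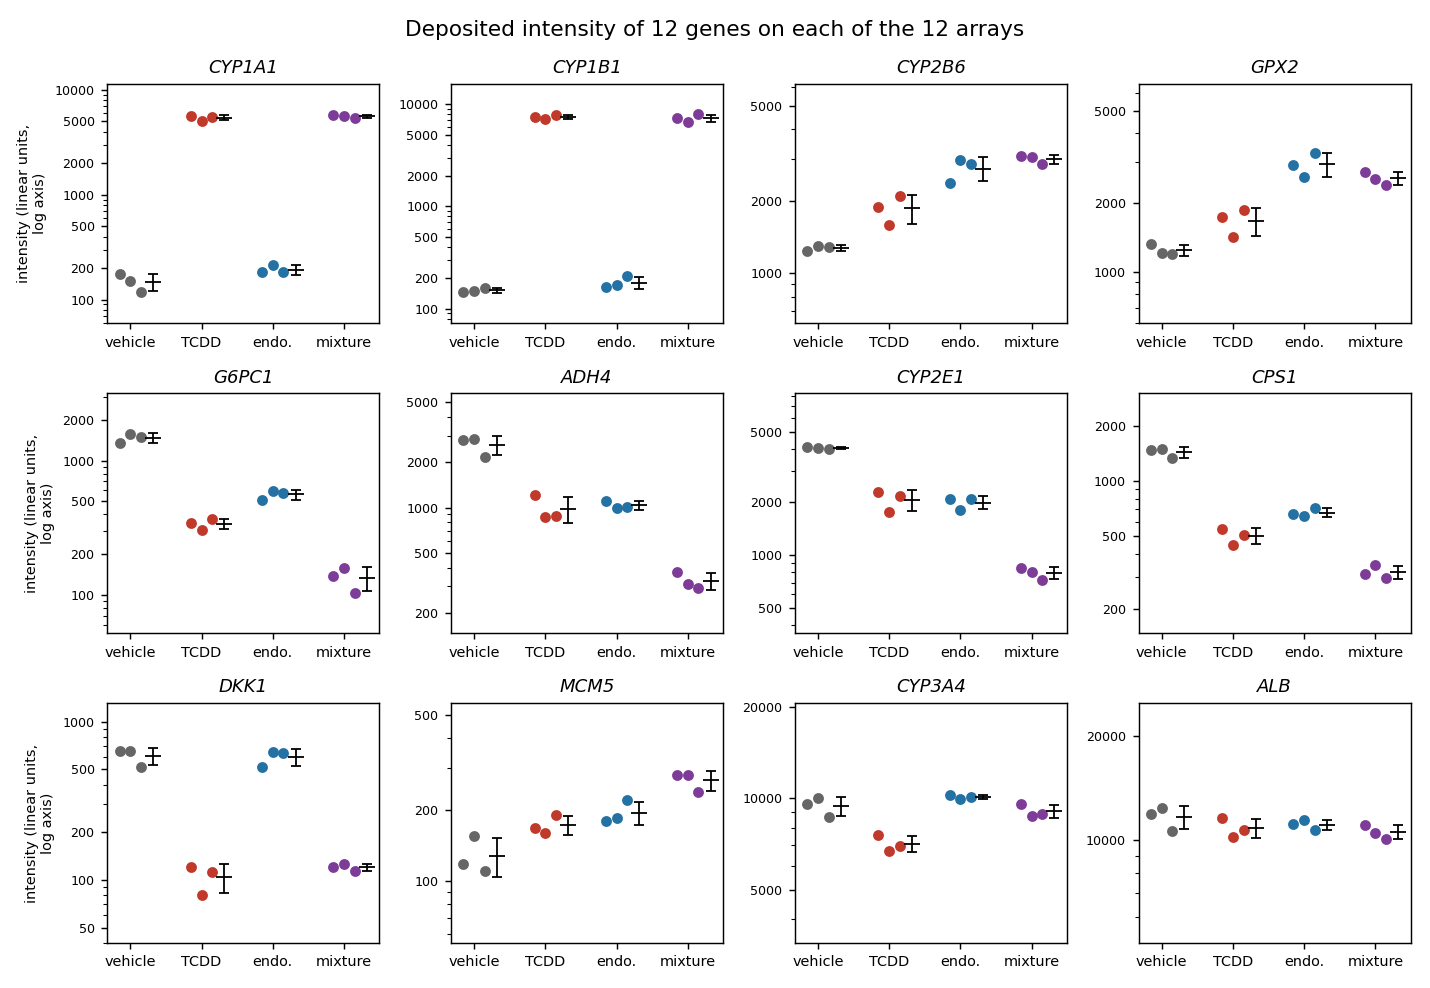
Deposited intensity (linear units on a log axis) of 12 genes, with a dot for each of the 3 arrays of each group (endo. is endosulfan) and black marks for the group mean ± SD. CYP1A1 and CYP1B1 were raised with TCDD and the mixture, and G6PC1 went from 1475 with vehicle to 338 with TCDD, 559 with endosulfan and 134 with the mixture.

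Endosulfan changed 40 genes and no AhR target among them (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.891). The strongest increases were GPX2, a glutathione peroxidase (probe set 7979658; 1243 ± 66.6 to 2924 ± 353, log2 1.22 ± 0.12, adjusted p = 8.27e-05), and CYP2B6, a P450 induced through CAR (probe set 8028963; 1278 ± 34 to 2737 ± 316, log2 1.08 ± 0.12, adjusted p = 0.000133). The CYP2B7P pseudogene, which can share signal with CYP2B6, rose by 0.91. GPRC5B, UBD, SPP1, SFRP4, the cystine transporter SLC7A11, EXO1 and NEIL3 rose by 0.82 to 1.04. The 10 largest decreases were G6PC1 (log2 -1.37 ± 0.13), ADH4 (-1.31 ± 0.14), GNMT (-1.16), CPS1, which starts the urea cycle (-1.07), the plasma protein AFM (-1.04), CYP2E1 (-1.03), ADH1A (-0.84), the transporters SLC22A10 and SLC22A7 (-0.76 and -0.71) and HRG (-0.70). CYP1A1 and CYP1B1 had values of 0.36 ± 0.12 and 0.22 ± 0.12 that did not pass (adjusted p = 0.37 and 0.525), and CYP3A4 one of 0.10 ± 0.10 (adjusted p = 0.677). CYP3A4 was among the brightest genes, at 9409 with vehicle and 10102 with endosulfan. Whether signal is compressed at such intensities was not tested, so its value does not exclude an increase.

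Among lists, the cell cycle genes had a median log2 value of 0.40 with endosulfan and all 25 members above 0. None passed over all genes and 23 passed when adjusted over the list alone (camera adjusted p = 4.43e-15, and 0.497 with an estimated correlation). NRF2 targets rose in 3 of 17 cases (8 over the list alone): SLC7A11 (0.86), SRXN1 (0.55) and HMOX1 (0.70), with adjusted p = 1.19e-06 by camera and 0.497 with an estimated correlation. Of 14 CAR and PXR targets, CYP2B6 and ALAS1 (0.59), the rate-limiting enzyme of heme synthesis, rose (5 over the list alone; camera adjusted p = 0.00799, and 0.541 with an estimated correlation). Of 17 dehydrogenases, ADH4, ADH6 (-0.61) and ADH1A fell (5 over the list alone; camera adjusted p = 9.36e-07, and 0.497 with an estimated correlation). The gluconeogenesis list passed downward by camera (adjusted p = 0.0165, and 0.533 with an estimated correlation) although its median was 0.03. G6PC1 was its single decrease over all genes (2 over the list alone). Among biliary markers, SPP1 rose (0.93) and the list did not pass (camera adjusted p = 0.158).

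In all, 40 genes changed with endosulfan, 26 higher and 14 lower (65% higher), against 26 and 36 with quantile normalization (41.9% higher) and 28 and 29 with array medians subtracted (49.1% higher). Single arrays moved this count by over 1.5 times: it was 20 without vehicle replicate 1, 17 without vehicle replicate 3, 17, 20 and 13 without endosulfan replicate 1, 2 and 3. The excess of higher genes ended without vehicle replicate 3 (8 higher and 9 lower) and without endosulfan replicate 3 (6 and 7), and the calls of SPP1 and SFRP4 ended with quantile normalization. Among the named decreases the call was lost under 11 settings for ADH1A, 10 for SLC22A7, 9 for ADH6, 8 for GNMT, 5 for HRG and 3 for SLC22A10, and for ADH1A, ADH6 and SLC22A7 without any single vehicle or endosulfan array. Among the increases it was lost under 13 for HMOX1, 12 for SRXN1 and ALAS1, 10 for SPP1, 6 for SFRP4 and NEIL3, 5 for GPRC5B and 2 for SLC7A11, and for HMOX1, SRXN1 and ALAS1 without any single vehicle or endosulfan array. By camera 17 lists passed, and 0 with an estimated correlation, while other divisions of the 6 arrays passed up to 12.

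The mixture raised 7 of 9 AhR targets (8 over the list alone) and lowered members of several metabolic lists. CYP1B1 (7304 ± 608), CYP1A1 (5587 ± 155) and CYP1A2 (2699 ± 401) rose 43.6-fold, 34.4-fold and 28.3-fold over vehicle, and STC2, SLC37A2, TMEM156, ALDH3A1, MB21D2, TIPARP and MBL2 were the next largest increases. G6PC1 fell to 134 ± 27.9 (log2 -3.33 ± 0.13, adjusted p = 4.21e-12), ADH4 (probe set 8101852) fell from 2604 ± 384 to 326 ± 41.8 (log2 -2.93 ± 0.14, adjusted p = 8.28e-11), and CYP2E1 (probe set 7931643), an ethanol-inducible P450, fell from 4077 ± 64.8 to 792 ± 62 (log2 -2.34 ± 0.12, adjusted p = 1.36e-10). HAO2 (-2.52), RDH16 (-2.43), SLC2A2 (-2.26), DKK1 (-2.19), GNMT (-2.14), CPS1 (-2.11) and MFSD2A (-1.93) completed the 10 largest decreases.

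Cell cycle genes rose together with the mixture: 18 of 25 passed over all genes and 24 when adjusted over the list alone, with a median of 0.56 (camera adjusted p = 4.3e-20, and 0.093 with an estimated correlation). The replication helicase subunits led, with MCM5 at 0.98, MCM2 at 0.92, MCM6 at 0.85 and MCM4 at 0.72. Of 17 NRF2 targets, 9 rose (11 over the list alone), among them SLC7A11 (1.81), SRXN1 (1.01), GCLM (0.87) and PGD (0.53), with an adjusted p of 3e-08 by camera and 0.129 with an estimated correlation. Metallothioneins and a zinc exporter formed a list of 9, of which 6 rose (8 over the list alone), with MT1G and MT1H at 0.56 (camera adjusted p = 1.28e-06, and 0.093 with an estimated correlation). In the list of cytokines and NF-kB targets, 5 of 18 rose and 1 fell (8 and 1 over the list alone): CCL20 had a value of 0.94, CCL2 of 0.69, CXCL8 of 0.55 and CXCL2 of -0.55 (camera adjusted p = 0.000312, and 0.129 with an estimated correlation).

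Several lists of metabolism, plasma proteins and hepatocyte markers were lowered in part. By camera other lists passed downward too, among them cholesterol synthesis, the circadian clock and lipogenesis (adjusted p = 0.000505, 0.000505 and 0.00494). With an estimated correlation these were 0.401, 0.36 and 0.52. Coagulation factors fell in 10 of 21 cases (11 over the list alone), with HRG at -1.20, PLG at -0.80 and KNG1 at -0.75 (camera adjusted p = 2.17e-16, and 0.093 with an estimated correlation). Dehydrogenases fell in 6 of 17 cases and 1 rose (8 and 2 over the list alone), including ADH1A at -1.86, ADH1B at -1.60 and ADH6 at -1.50, and gluconeogenesis genes fell in 6 of 14 cases (7 fell and 1 rose over the list alone), with adjusted p = 0.093 for both lists with an estimated correlation. For the urea cycle and amino acid list, 6 of 17 fell (7 fell and 2 rose over the list alone), including OTC (-1.09) and ARG1 (-1.24), and in the bile acid list 7 of 16 fell and AKR1D1 rose by 1.48 (10 and 2 over the list alone). With an estimated correlation their adjusted p was 0.129 and 0.093. Fatty acid oxidation genes fell in 6 of 21 cases (9 over the list alone), including ACAA1 (-0.78) and EHHADH (-0.70), and conjugation enzymes in 6 of 23 (10 over the list alone), including UGT2B17 (-1.74) and SULT1B1 (-0.86), with adjusted p = 0.093 and 0.129 with an estimated correlation. Of 14 hepatocyte markers, AFM (-1.83) and AHSG (-0.85) fell, while ALB had a value of -0.14 (adjusted p = 0.616; camera adjusted p = 1.76e-06, and 0.163 with an estimated correlation; 2 also fell over the list alone). NR1I3, which encodes CAR, had a value of -0.66 and the transcription factor PROX1 of -0.60, both past the threshold. CYP2B6 rose by 1.22 and CYP2C8 had a log2 change of -0.76. CYP3A4 had a value of -0.05 (adjusted p = 0.888), to be read, like that of ALB, with the limit at high intensities given above. Beside these, the biliary markers SPP1 (0.94) and ANXA4 (0.43) and the mesenchymal LUM (0.86) and COL1A1 (0.49) rose, and POSTN (-0.81) and KDR (-1.21) were lower.

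The mixture changed 937 genes against vehicle, 586 higher and 351 lower (62.5% higher), while quantile normalization gave 677 and 619 (52.2% higher). The count was 581 without vehicle replicate 1, 597 without vehicle replicate 3 and 571 without mixture replicate 3. The excess of higher genes ended without vehicle replicate 3 (287 higher and 310 lower) and nearly so without mixture replicate 2 (367 and 336), and the higher genes numbered 344, 382 and 363 without vehicle replicate 1, mixture replicate 1 and mixture replicate 3. Of the 937 genes, 473 changed at least 1.5-fold. By camera 25 lists passed, 8 upward and 17 downward, and with an estimated correlation 1, the AhR targets (adjusted p = 0.00271). Other divisions of the 6 arrays passed up to 19 lists. Calls were lost under 7 settings for COL1A1, 6 for ANXA4, 3 for CXCL2, 2 for CXCL8 and MT1H, and 1 for ARG1, PGD, MT1G and UGT2B17.

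**Figure D2:**
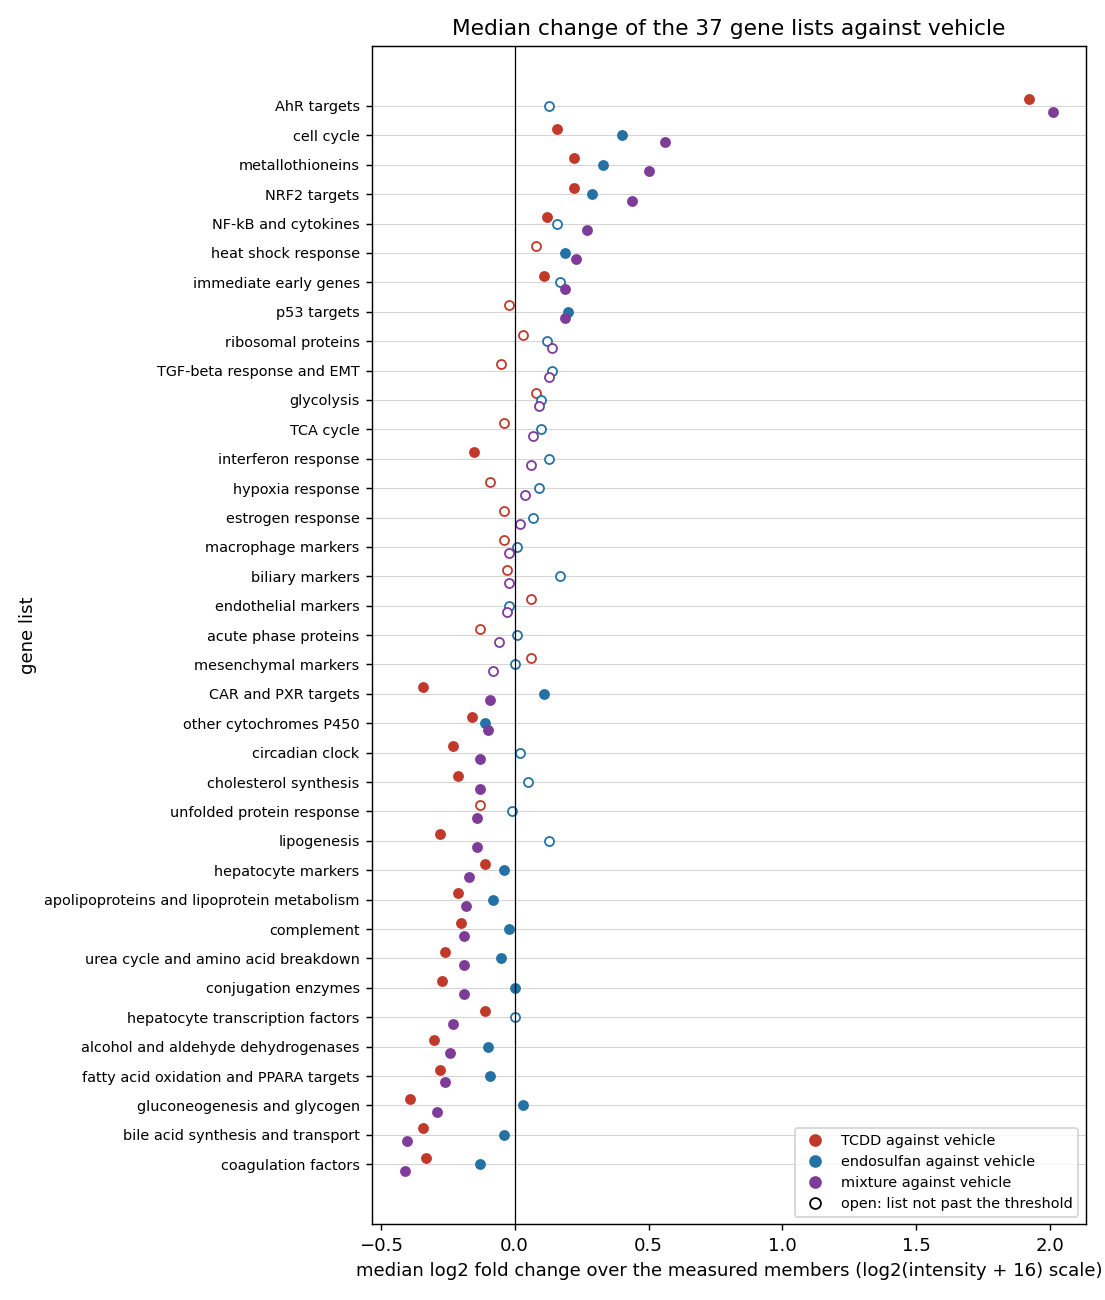
Median log2 fold change of the measured members of each of the 37 lists (horizontal axis), for TCDD (red), endosulfan (blue) and the mixture (purple) against vehicle, with filled circles where camera passed at the preset correlation. The AhR targets stand at 1.92 with TCDD, 0.13 with endosulfan and 2.01 with the mixture, and the cell cycle list at 0.16, 0.40 and 0.56.

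Set directly against TCDD, the mixture lowered several alcohol dehydrogenases, CYP2E1 and G6PC1 further. ADH4 fell from 985 ± 198 to 326 ± 41.8 (log2 -1.54 ± 0.14, adjusted p = 2.25e-05), CYP2E1 from 2072 ± 282 to 792 ± 62 (-1.36 ± 0.12, adjusted p = 1.45e-05) and G6PC1 from 338 ± 30.9 to 134 ± 27.9 (-1.25 ± 0.13, adjusted p = 0.000119). ADH1A (-1.14) and ADH1B (-0.98) fell as well, so that with ADH6 (-0.66) 4 of 17 dehydrogenases were lower (5 over the list alone; camera adjusted p = 1.09e-06, and 0.591 with an estimated correlation). In the gluconeogenesis list, G6PC1 and SLC2A2 (-0.86) were the only 2 of 14 that fell (2 over the list alone), and the median was -0.01 with 7 values on each side of 0 (camera adjusted p = 0.0271, and 0.591 with an estimated correlation). DTL, part of a ubiquitin ligase active in S phase (0.97), GPRC5B (0.89), SFRP4 (0.88), FAM111B (0.84) and UBD (0.82) were the largest increases, and CYP2B6 rose by 0.69. In the cell cycle list, MCM6 passed over all genes (0.62) and 20 of 25 over the list alone, with a median of 0.37 (camera adjusted p = 3.42e-08, and 0.591 with an estimated correlation). No AhR target passed over all genes (1 lower over the list alone): CYP1A1 and CYP1B1 had values of 0.04 ± 0.12 and -0.04 ± 0.12, and CYP1A2 one of -0.59 ± 0.14 (adjusted p = 0.115).

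This comparison called 44 genes, 30 higher and 14 lower (68.2% higher), and its split turned with the scaling, to 13 and 24 with quantile normalization (35.1% higher) and 14 and 21 with array medians subtracted (40% higher). Over all genes the median log2 value was 0.1, and the calls of GPRC5B and SFRP4 ended with quantile normalization. Calls were lost under 15 settings for MCM6, 13 for GPRC5B, 11 for SFRP4, 9 for CYP2B6, 7 for ADH6 and FAM111B, 4 for UBD and 2 for ADH1A and SLC2A2. For MCM6, CYP2B6 and ADH6 these included a fit of only the groups compared and the omission of any single mixture array. The count was 27 without vehicle replicate 1, 15, 12 and 163 without TCDD replicate 1, 2 and 3, 29 without endosulfan replicate 1, and 10, 14 and 15 without mixture replicate 1, 2 and 3. The split turned to 3 higher and 9 lower without TCDD replicate 2, 2 and 8 without mixture replicate 1, and 3 and 11 without mixture replicate 2. Fitting only the 2 groups compared gave 5 genes. By camera 16 lists passed, and 0 with an estimated correlation.

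Against endosulfan, the mixture differed by the AhR response and by further decreases. CYP1A2 rose 37.7-fold, CYP1B1 37.4-fold, CYP1A1 26.8-fold and SLC37A2 7.51-fold, and 6 of 9 AhR targets rose (8 over the list alone; camera adjusted p = 1.57e-47, and 0.000387 with an estimated correlation). STC2 rose as well, from an intensity of 3.66 with endosulfan that lay below the offset, so that its log2 change depends on the offset (3.76, and 5.08 with an offset of 4). The largest decreases were DKK1 (-2.17 ± 0.14), G6PC1 (-1.96 ± 0.13), HAO2 (-1.88), MFSD2A (-1.76) and SLC2A2 (-1.71). ADH4 (-1.62), ADH1B (-1.02) and CYP2C8 (-0.87) were also lower, while CYP2B6 had a value of 0.14 ± 0.12 (adjusted p = 0.998). CAR and PXR targets fell in 5 of 14 cases (7 over the list alone), led by THRSP (-1.30) and SULT2A1 (-0.84), with a camera adjusted p of 2.91e-09 and of 0.259 with an estimated correlation. The comparison called 265 genes, 94 higher and 171 lower, and 139 without mixture replicate 3 (58 and 81). Without endosulfan replicate 3 the excess of lower genes ended, with 98 higher and 92 lower. By camera 24 lists passed, and with an estimated correlation 1, the AhR targets.

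The mixture was then set against the sum of its parts. This takes the mixture to hold each compound at its single dose, which the labels do not state separately. No gene departed from additivity on the log2 scale by limma (0 of 18416; smallest adjusted p = 1). At an unadjusted p under 0.05 there were 185 genes, where chance gives 921, and the median SE of the departure was 0.178. In simulated arrays of this design, with genes drawn independently, 7.5% of departures of 0.5 and 71.6% of departures of 1 were recovered. Departures of 0.5 were thus rarely recovered there. Independent unchanged arrays gave 887 to 982 genes at an unadjusted p under 0.05, far from 185, so these shares may not hold for the real arrays. The smallest p-values upward belonged to STC2, HEMGN, CD4, KIRREL2 and ZNF175, and downward to GPX2 (-0.60 ± 0.18), ELSPBP1, ABHD16B, ZNF660 and LINC03069. STC2 lay below the offset with vehicle and endosulfan, HEMGN in all 4 groups, ZNF660 with the mixture, and LINC03069 with vehicle and the mixture, so that their values depend on the offset (for STC2 0.68, and 0.94 with an offset of 4). For G6PC1 the departure was 0.12 ± 0.19, for ADH4 -0.23 ± 0.20, for CYP1A1 -0.32 ± 0.18 and for CYP2B6 -0.39 ± 0.17. Among the 937 genes changed by the mixture, its log2 changes correlated with the sum of the single changes at 0.987 across genes, with a slope of 0.936. Over all 18416 genes the correlation was 0.868 and the slope 0.748. Both sides share the vehicle arrays: in simulated unchanged groups the correlation was 0.578 (slope 0.334) over all genes and 0.83 (slope 0.692) over the 937 genes with the smallest p for the mixture. Genes are not independent replicates. Among the 452 TCDD genes, 360 changed less in the mixture than the sum, a direction that selecting genes on the TCDD arrays can itself give. The number was 561 of the 937 mixture genes and 11007 of all 18416 genes, and unchanged groups were not counted this way. The sum carries the noise of both single changes, each with the vehicle arrays in it. Noise alone thus tends to make the sum larger than the mixture change, as the simulated slopes below 1 show. These counts therefore do not show that the mixture fell short of the sum. Only the NRF2 targets passed among lists, with 15 of 17 below 0 and a median of -0.09 (camera adjusted p = 0.00202, and 0.979 with an estimated correlation).

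**Figure D3:**
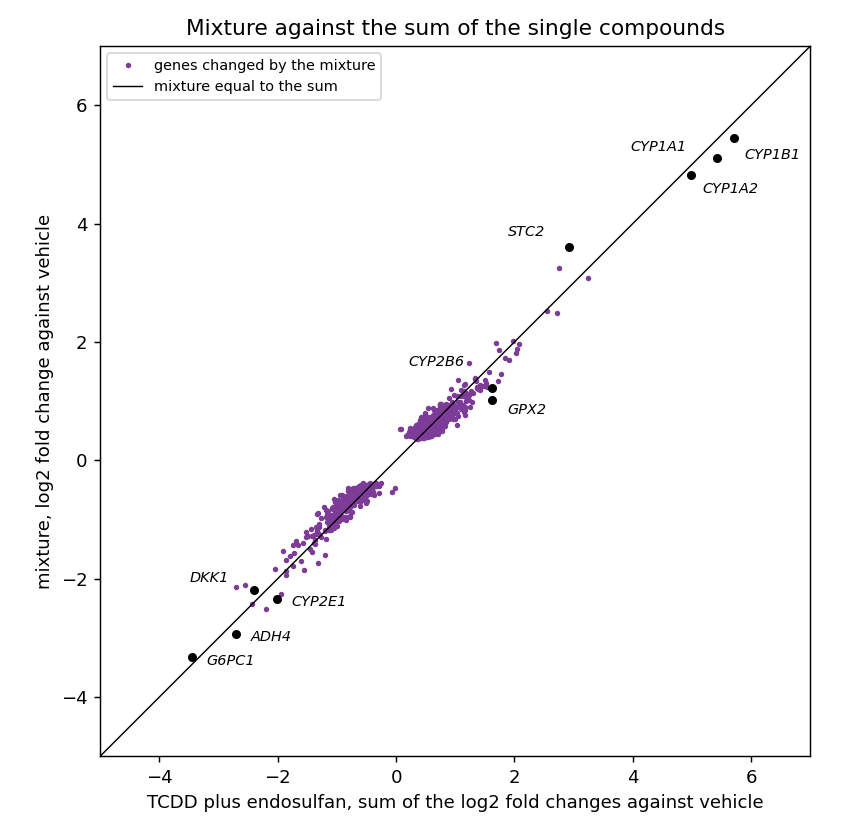
Log2 fold change of the mixture against vehicle (vertical axis) and the sum of the TCDD and endosulfan log2 fold changes (horizontal axis) for the 937 genes changed by the mixture, with the line of equality and 10 genes labelled. The correlation across these genes was 0.987 with a slope of 0.936 (0.868 and 0.748 over all genes, and 0.83 and 0.692 over as many genes selected in simulated unchanged groups), and the gap around 0 comes from plotting only called genes.

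Responses to the single compounds shared genes. Of the 40 endosulfan genes, 23 were also called with TCDD, all in the same direction, 10 higher and 13 lower, where independent lists would share 0.2 and 0.3. Unchanged groups simulated against the shared vehicle arrays shared 0 and 0.01 on average, but such groups give few calls to share, so this says little about lists of this length. With 3 vehicle arrays no split leaves 2 on each side, so part of the excess may come from the shared vehicle arrays. The shared genes included G6PC1, ADH4, CPS1, CYP2E1, AFM, GNMT, CYP2B6, SLC7A11 and EXO1. Over all 18416 genes, in contrast, the TCDD and endosulfan responses correlated at 0.092 (Spearman -0.016), below the 0.499 of unchanged groups, and their covariance was 0.0034 against a simulated 0.0103, a difference of -0.0069. The simulated genes were drawn independently and without array-wide shifts, so these differences do not show opposed responses. The mixture response correlated with that of TCDD at 0.663 (0.5 in unchanged groups) and with that of endosulfan at 0.624 (0.499), and the covariance lay above the simulated 0.0103 by 0.0258 and 0.0158. By rank (Spearman) the correlation was 0.384 with TCDD and 0.683 with endosulfan, against 0.472 in unchanged groups for each. For TCDD the excess over unchanged groups was thus not seen by rank. Of the 937 mixture genes, 353 were also called in the same direction with TCDD (103 higher and 250 lower, against 3.6 and 6.5 for independent lists) and 38 with endosulfan (24 and 14, against 0.8 and 0.3), while 569 were called with neither. Being called with neither does not show these to be specific to the mixture. By limma no gene was called as departing from the sum (0, and 185 at an unadjusted p under 0.05). That does not show additivity for these genes either, since departures of 0.5 were rarely recovered in the simulated arrays (7.5%).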

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

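Of the tests in this part, the counts in other splits of the arrays, the replicate block and the shuffles of residual arrays were planned before their results were seen, and the test by quantile normalization was chosen afterwards. Probe sets without a single gene name, which no comparison used, also changed: of 13837 such probe sets, 57 with TCDD, 2 with endosulfan and 103 with the mixture passed the threshold against vehicle when every probe set was tested. The NRF2 targets were singled out because they were the only list that camera passed for the departure, with a median departure of -0.09. No member passed over all genes or over the list alone. The camera adjusted p of the list was 0.00202 with the preset correlation and 0.979 with an estimated correlation, and by fry it was 0.985.

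The departure from additivity gave 185 genes with an unadjusted p under 0.05, fewer than the 921 that chance gives. In 20 simulated sets of independent unchanged arrays the number ran from 887 to 982. Effects shared by arrays of a replicate number are argued against as the whole cause, since the number was 288 with the replicate block, under the 460 set as its bound, and array scale likewise, since it was 344 after quantile normalization. What stays open is chance with genes that move together across arrays: in 20 of 100 shuffles of the 12 residual arrays the number was as low, and it ranged from 0 to 5260. No biological explanation was tested.

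Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. In each, the real split alone reached its count (1 of 10). The real counts of genes and the highest of the other splits were 452 and 0 for TCDD against vehicle, 40 and 0 for endosulfan, 937 and 0 for the mixture, 44 and 2 for the mixture against TCDD, and 265 and 0 against endosulfan. For gene lists by camera they were 23 and 12, 17 and 12, 25 and 19, 16 and 12, and 24 and 11 in the same order. Every other split keeps part of the treatment difference, since it sets 2 arrays of a group and 1 of the other against the rest, so lists passing there are no measure of chance alone. For the departure, 100 groupings of the 12 arrays were drawn. Any grouping reaches its count of 0 genes, so they say nothing of that count, and the highest was 1138. For its 1 list, 84 of the 100 gave at least as many, up to 26, so chance is not excluded for that list.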

How the results depend on the processing

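Offsets, gene-by-gene array weights, removal of the 3 arrays with extreme upper quartiles, and quantile normalization of the list counts and of the response correlation were chosen after seeing the data. Named list members included, 301 values of named genes passed the threshold, and none of them turned direction in the alternatives run. Of these, 191 kept their call under all alternatives and 110 lost it at least once, under up to 17 settings (HRG in the mixture against TCDD). Next came OASL with TCDD and SLC7A11 in the mixture against TCDD (16 each), then CYP3A4 and CYP39A1 with TCDD and MCM6 in the mixture against TCDD (15 each). By limma the departure from additivity gave 0 genes under each alternative run, with 185 genes at an unadjusted p under 0.05, 344 after quantile normalization and 108 with an offset of 64.

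For the values that follow the cause was not tested, except that a fold minimum can only remove genes. A 1.5-fold minimum gave 272 genes for TCDD and 473 for the mixture against vehicle. Every probe set gave 15 for endosulfan and 8 for the mixture against TCDD. Fitting only the groups compared gave 74 and 5 for these. Quantile normalization gave 62 for endosulfan, and an offset of 4 gave 18 for endosulfan and 10 for the mixture against TCDD. Without the 3 arrays with extreme upper quartiles these were 19 and 14. Array weights gave 5304 for TCDD, 674 for endosulfan, 2506 for the mixture, 6379 for the mixture against TCDD and 594 against endosulfan, but the estimate did not converge and gave TCDD array 1 a weight of 37.24. Estimated gene by gene, the weights gave 1926, 402, 2179, 2215 and 569. Leaving out each array in turn gave 235 to 519 genes for TCDD, 13 to 50 for endosulfan, 571 to 1111 for the mixture, 10 to 163 for the mixture against TCDD and 139 to 316 against endosulfan.

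With the replicate number as a block, the counts were 630, 82, 1186, 96 and 379 for the 5 comparisons in that order. The numbers are not shown to pair the samples: 14 of 18 same-number pairs correlated above 0.1 in their deviations from group means, with a lowest value of -0.382. As a hint from the data, 11 of 12 samples correlated best, among samples of other groups, with one of their own number. The median correlation was 0.2875 for same-number pairs and -0.1645 for other pairs. A shared origin of same-number samples thus stays possible, and the main p-values leave it out.

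The 23, 17, 25, 16, 24 and 1 lists passed by camera became 1, 0, 1, 0, 1 and 0 with an estimated correlation. With fry they were 14 for TCDD, 2 for endosulfan, 21 for the mixture, 0 for the mixture against TCDD, 8 against endosulfan and 0 for the departure, which tests another question than camera does. For the departure, 2 lists passed without the dimmest genes and 3 without the arrays with extreme upper quartiles. The correlation of the TCDD and endosulfan responses, 0.092, was 0.156 after quantile normalization and 0.499 in simulated unchanged groups of independently drawn genes. Between 14.9% and 17.2% of an array lay under the offset, which limits folds of dim genes.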

Other observations

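Among tests in this part, the count of metabolic genes kept after quantile normalization was planned before its result was seen, and the others were chosen afterwards. Further genes changed with the mixture. Of 20 glycolytic genes, PFKP (1.14) and HK2 (0.80) rose, while PKLR, the liver pyruvate kinase (-1.01), and PFKFB1 (-1.43) were lower (3 higher and 2 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.483). GDF15, a stress-induced cytokine, rose by 1.42 with TCDD and 1.74 with the mixture and had a value of 0.42 with endosulfan that did not pass. IER3 (1.89), MYC (1.01) and FOS (0.48) rose with the mixture among 16 immediate early genes (the FOS call was lost under 7 settings; 5 adjusted over the list alone; camera adjusted p = 0.000454, and 0.193 with an estimated correlation). CA12, a carbonic anhydrase, rose in all 3 comparisons against vehicle, by 0.77 with TCDD, 0.66 with endosulfan (a call lost under 2 settings) and 1.26 with the mixture. PPP1R15A (0.72) and ATF3 (0.54) rose and XBP1 was lower (-0.43) among 22 genes of the unfolded protein response (the ATF3 and XBP1 calls were each lost under 7 settings; 2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.00746 downward, and 0.401 with an estimated correlation).

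Lower expression of hepatocyte metabolic genes in the mixture covered 47 genes of 7 lists, with a median of -0.77. A smaller share of hepatocyte-like cells would lower hepatocyte-made genes together, and their spread argues against it as the whole cause. The 46 such genes with vehicle intensities from 100 to 5000 had an SD of 0.39 across genes against a median SE of 0.12. They ranged from -1.83 to 0.28, with a median of -0.27. The medians of the 47 and the 46 are not comparable, since only the 47 were picked for being lower. Coagulation factors are in both sets. After quantile normalization 100% of the 47 calls remained. That count is a weak test, since 899 of all 937 mixture calls remained and lowered genes rose from 351 to 619. The median over all genes moved from 0.038 to 0.003, little beside -0.77, which argues against array scale as the whole cause. More biliary-like or mesenchymal cells in place of hepatocyte-like cells stay open, since 28 of their markers had a median of -0.06 and went both ways, and the 0.3 that such a shift was taken to need lies within their SD of 0.36 of that median. A change of expression within hepatocyte-like cells may also account for it, as a hypothesis from the same arrays.

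The excess of raised genes with the mixture and of lowered genes with TCDD was weighed against array scale. After quantile normalization the raised share was 52.2% with the mixture, from 62.5%, so array scale may account for that excess. The excess also ended without vehicle replicate 3 alone (287 higher and 310 lower), so it rests on that array too. With TCDD it was 35.6%, from 24.8%, so scale moved that share without removing the excess of lowered genes. Whether the treatments change the total RNA of these cells was not tested here.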
